A study of Homo sapiens with 12 samples.

How the data were processed

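Total RNA of BT549 cells was measured on Affymetrix human gene arrays in 4 groups of 3 arrays: control siRNA or c-Jun siRNA for 72 hours, each followed by vehicle or TNFα for 6 hours. Groups and replicate numbers were taken from the sample labels. The labels do not say that replicates were separate cultures, so the p-values measure the spread between these samples. Per the labels, the authors named Affymetrix Expression Console 1.1 and PLIER among their processing tools without giving each one's role. The deposited values are used here as log2 expression per probe set. The logarithm's base was inferred from their range of 2.27 to 14.0, and their common scale from quartiles that differ between arrays by at most 0.061. They were not normalised further. Array medians lay between 5.62 and 5.68. The number of arrays limits the precision.

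The value table held 33297 probe sets: 19181 with 1 gene symbol, 2055 with several and 12061 without a symbol here. Genes were taken from the probe sets with 1 symbol, of which 19140 had an Entrez identifier in the gene table. Where a gene had more than 1 (895 genes), the probe set with the highest mean over the 12 arrays was used, which gave 17958 genes, with no filter on dim ones. Probe sets with several symbols or none were left out of the comparisons and tested apart. limma 3.58.1 in R 4.3.3 fitted one mean per group to all 12 arrays, with 8 residual degrees of freedom, moderated variances with a mean-variance trend (prior degrees of freedom 9.29) and contrasts for TNFα under each siRNA, c-Jun siRNA under each treatment, and their interaction. Tests were two-sided, Benjamini-Hochberg adjustment ran over all genes of a comparison, and a gene was called changed at an adjusted p under 0.05. Errors of log2 fold changes are standard errors from this fit, and errors of group means are SDs over 3 arrays. Tables were handled in Python 3.11.15 with pandas 2.3.3, and plots drawn with matplotlib 3.10.9.

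The comparisons, the gene lists, the rule for naming genes and all alternatives but one were chosen before the data were examined. The 25 lists had 513 entries, of which 465 were measured, 5 of them under a newer symbol. Another 12 were only on probe sets of several genes and 36 were not named by the probe table. Lists were tested with camera in limma at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over 25 lists and 5 comparisons. camera called 49 of the 125 list results, and 32 of these calls held with an estimated correlation. Where a call did not hold, the second p stands beside it. The alternatives used the camera variant on moderated statistics, which called 52, of which 46 were also called by camera. It did not call 3 that camera called: the mitosis list for TNFα with control siRNA, and the mitosis and hypoxia lists for c-Jun siRNA with vehicle.

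Named genes are JUN, ZEB2, a transcription factor gene followed in this study, and AP-1 family members. For each pairwise comparison the rule adds the 10 largest rises and 10 largest falls among changed genes whose 3 arrays in one group all lay above the 3 of the other, a separation that chance gives for 10% of genes. It adds up to 4 changed members per list with the largest absolute change, and for the interaction up to 10 genes with the smallest p. Some genes that the rule takes are not reported here. Overlaps of called genes were set against the number expected for independent calls. Where a pair of comparisons shares control arrays, 20 simulations without a c-Jun siRNA effect gave the number with no effect. Another 20, chosen after seeing the data, kept the called effects and shuffled those of c-Jun siRNA among genes in 20 bins of mean expression, and 20 more did so for the interaction.

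On simulated data with 200 seeded changes among 17958 genes, the pairwise tests recovered 52.2% to 68.7% of changes of 0.25 log2 units, 98.5% to 100% of changes of 0.5 and all of 1. The interaction test recovered 26.9%, 79.1% and 100%. Of the calls 4.79% to 9.62% were false. The real pairwise comparisons called 28.5% to 35.7% of genes and the interaction 5.47%, far more than were seeded. The adjusted threshold depends on that share, so recovery there may differ.

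Alternatives were floors on low values, quantile normalisation, centring on array medians, filters on dim genes, the mean of a gene's probe sets or every probe set by itself, other variance models, array weights, fits of only the compared groups, stricter thresholds, a replicate block and each array left out in turn. The position code in the array names was read as a column of a plate, which is an inference, and its column served as a fixed or a random block. An array whose name reads as a second run of c-Jun siRNA TNFα replicate 1 was also averaged with that replicate. Comparisons within a position column were chosen after seeing the data.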

Results

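Gene expression was measured in BT549 cells, a triple-negative breast cancer line that lacks the oestrogen and progesterone receptors and HER2 amplification. The cells carried a control siRNA or a pool of siRNAs against c-Jun for 72 hours and then received vehicle or tumour necrosis factor alpha (TNFα), an inflammatory cytokine, for 6 hours. c-Jun, the product of JUN, is a subunit of the AP-1 transcription factor, and the design asks which part of the TNFα response depends on it. Each of the 4 groups holds 3 arrays, 12 in all. Values are log2 expression per probe set, and 17958 genes were compared. Array medians lay between 5.62 and 5.68, and the arrays' number limits the precision. Over all genes, the median standard error of a log2 fold change was 0.065 between a pair of groups and 0.092 for the interaction. The first principal component held 62.1% of the variance and parted the vehicle arrays from the TNFα arrays. The second held 24.4% and parted the siRNAs.

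JUN itself fell with the c-Jun siRNA in both treatments and rose with TNFα under both siRNAs. Its mean log2 expression (probe set 7916609) was 10.35 ± 0.0052 (SD, n = 3) with control siRNA and vehicle, and 11.07 ± 0.041 with control siRNA and TNFα. With c-Jun siRNA it was 9.83 ± 0.021 with vehicle and 10.36 ± 0.032 with TNFα, so that JUN in the knocked-down, TNFα-treated cells stood at the level of untreated control cells. The knockdown left 69.5% of the JUN signal with vehicle (log2 fold change -0.52 ± 0.032, SE) and 61.1% with TNFα (-0.71 ± 0.032). TNFα raised JUN by 0.72 ± 0.032 with control siRNA and by 0.53 ± 0.032 with c-Jun siRNA. The difference between those responses was -0.19 ± 0.045 (adjusted p = 0.0173). That call ended without the mean-variance trend (adjusted p = 0.0806), with the position column of the arrays as a fixed block (0.0554) and without control siRNA TNFα replicate 1 (-0.16, 0.054), over a range of 0.0102 to 0.0806 in 28 alternatives. ZEB2, a zinc-finger repressor of epithelial genes, followed the same order (probe set 8055624). TNFα raised it by 1.07 ± 0.039 with control siRNA and by 0.69 ± 0.039 with c-Jun siRNA, while the knockdown changed it by -0.41 ± 0.039 with vehicle and by -0.78 ± 0.039 with TNFα. Its interaction was -0.38 ± 0.055 (adjusted p = 0.000248). A second ZEB2 probe set with a mean of 3.52 changed with TNFα and control siRNA (0.53), and its other 4 tests did not pass. With the mean of both probe sets the vehicle call (-0.22, adjusted p = 0.0625) and the interaction call (-0.35, adjusted p = 0.12) ended. Over 28 alternatives those adjusted p-values ran from 2.68e-08 to 0.0625 and from 7.92e-05 to 0.12.

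**Figure D1:**
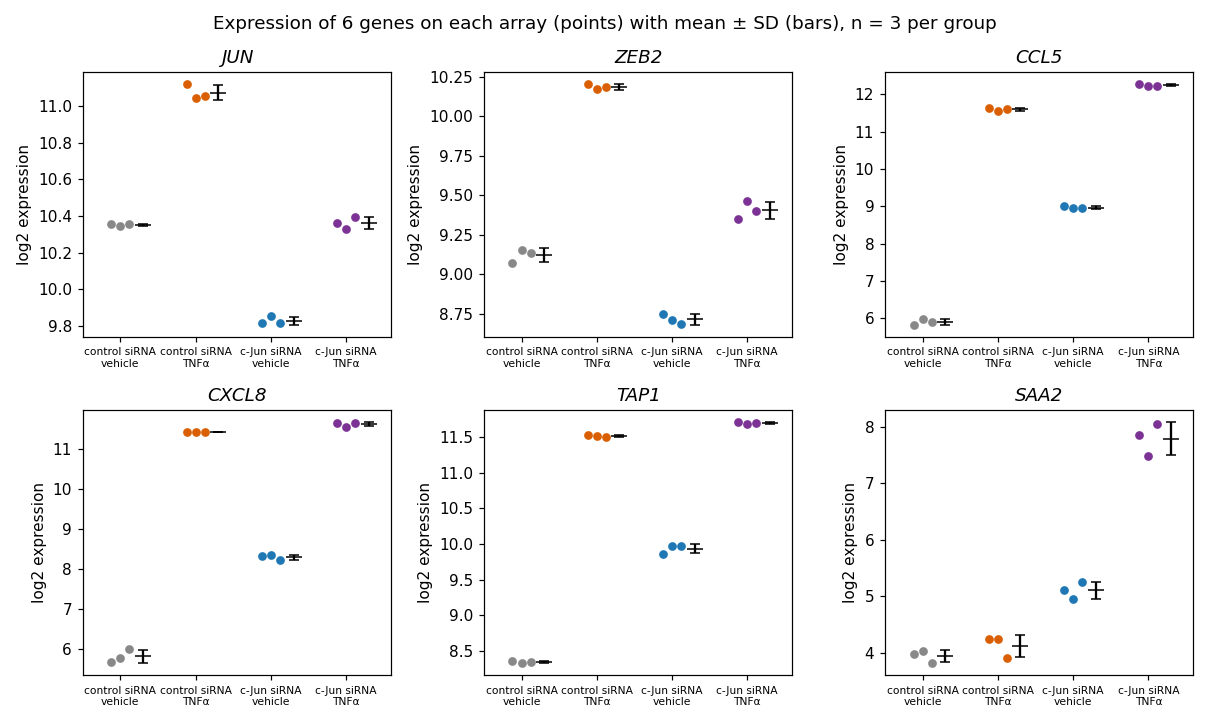
Log2 expression of JUN, ZEB2, CCL5, CXCL8, TAP1 and SAA2 on each of the 12 arrays (points) in the 4 groups, with mean ± SD (bars, n = 3). JUN with c-Jun siRNA and TNFα averaged 10.36, close to the 10.35 of control siRNA with vehicle, and CCL5 with c-Jun siRNA and vehicle averaged 8.97 against 5.90 in its control.

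The effect of TNFα with control siRNA shows the response of cells with c-Jun at its own level. CXCL10, a chemokine that draws T cells, rose by 8.06 ± 0.10 (log2, SE, n = 3 per group), from a mean of 3.48 to 11.53. The adhesion molecule VCAM1 rose by 6.79 ± 0.057 and the NF-kB target TNFAIP2 by 6.79 ± 0.067. TNFAIP6, a secreted hyaluronan-binding protein, rose by 6.38 ± 0.078. The chemokines CCL5 and CXCL8 rose by 5.71 ± 0.041 and 5.59 ± 0.061. Among interferon-stimulated genes, XAF1, MX1, SAMD9L and IFIH1 rose by 5.54, 5.46, 5.14 and 4.88. All of these genes but CCL5 and CXCL8 started at 3.48 to 5.44, below the array medians. The background limits how exactly their rises are known, and those of other genes with such starts, among them OAS2 (4.64). The deepest falls were smaller in size, in PPDPFL (-2.46 ± 0.11), in BOC, a co-receptor of Hedgehog signalling (-2.20 ± 0.10), in TMEM37 (-1.99) and in the protocadherin PCDH18 (-1.98). The phosphodiesterase PDE8B, the homeobox gene HOXB6, and TRERF1, BRINP1, SLITRK6 and EEPD1 followed, from -1.90 to -1.68. The standard errors of the 118 genes named by the fixed rule ran from 0.028 to 0.13. In all, 6416 of the 17958 genes changed at a limma adjusted p under 0.05. Of these 2486 were higher and 3930 lower, and 322 rose and 101 fell at least 2-fold.

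Inflammatory lists rose as a whole with TNFα and control siRNA. All 22 measured NF-kB early response genes rose, 22 also when adjusted over the list alone, with a median log2 fold change of 2.17 (camera adjusted p = 3.83e-38). Among them TNFAIP3, which restrains NF-kB signalling, rose by 4.37 and the inhibitor NFKBIA by 3.10. Of 28 cytokines and chemokines 22 rose and none fell (23 adjusted over the list alone), with EBI3 at 3.91 beside CXCL10, CCL5 and CXCL8 (median 1.52, adjusted p = 1.47e-26). That median ran from 1.30 to 3.63 over 28 alternatives. Of 28 interferon-stimulated genes 26 rose (27 adjusted over the list alone; median 2.64, adjusted p = 9.3e-38), with the antiviral OAS2 at 4.84. All 13 genes of MHC class I presentation rose (13 adjusted over the list alone; median 1.62, adjusted p = 9.89e-23), among them the peptide transporter TAP1 at 3.16, the immunoproteasome subunit PSMB9 at 2.16 and HLA-B at 1.88. Of 17 TNF receptor signalling components 11 rose and 2 fell (the same counts adjusted over the list alone), with the deubiquitinase CYLD at 2.31 and BIRC2 at 0.99 (adjusted p = 8.1e-05). Of 21 apoptosis regulators 11 rose and 3 fell (the same counts adjusted over the list alone), led by PMAIP1 at 1.46 (adjusted p = 0.000491).

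AP-1 genes and other programmes changed as well. In the AP-1 family 7 of 16 genes rose and 4 fell (8 and 4 adjusted over the list alone), with JUNB at 1.30, MAFF at 1.63 and FOSL1 at 0.62 above, and FOS at -0.40 and ATF2 at -0.18 below. That list passed at adjusted p = 0.0209, but adjusted p = 0.307 with an estimated correlation. Of 25 AP-1 target genes 17 rose and 2 fell (18 and 2 adjusted over the list alone; median 0.34, adjusted p = 6.04e-09), among them the matrix proteases MMP1 at 2.63, MMP3 at 1.69 and MMP9 at 1.44. The median of that list ran from 0.195 to 0.391 over 28 alternatives. Hypoxia and glycolysis genes fell, 16 of 20 with none rising (16 adjusted over the list alone; median -0.34, adjusted p = 1.68e-09). They include the glycolytic regulator PFKFB4 at -1.64, PDK1 at -1.03, the mitophagy gene BNIP3 at -0.91 and the histone demethylase KDM3A at -0.73. YAP/TEAD target genes rose in 10 cases and fell in 3 of 21 (the same counts adjusted over the list alone; adjusted p = 0.000777), with the matricellular CCN1 at 1.34. Of 15 p53 target genes 8 rose and 3 fell (8 and 4 adjusted over the list alone), with the cell-cycle inhibitor CDKN1A at 1.24 and ZMAT3 at 1.05. Their test gave adjusted p = 0.0055, and adjusted p = 0.0502 with an estimated correlation. Of 27 mitosis genes 17 fell and 2 rose (the same counts adjusted over the list alone), with the phosphatase CDC25C at -0.43 and DLGAP5 at -0.26. This gave adjusted p = 0.0125, and adjusted p = 0.471 with an estimated correlation.

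Other lists did not shift as a whole with TNFα and control siRNA. Of 18 mesenchymal genes 4 rose and 9 fell (4 and 12 adjusted over the list alone), ZEB2 against the cadherin CDH11 at -0.73 and the transcription factor SNAI1 at -0.46. Of 18 epithelial genes 3 rose and 1 fell (3 and 1 adjusted over the list alone), with the tight-junction gene CLDN1 at 2.37. Of 28 genes of extracellular matrix and adhesion 9 rose and 12 fell (10 and 12 adjusted over the list alone), with tenascin TNC at 1.08, the collagen COL3A1 at 0.95 and the protease inhibitor TIMP3 at -1.26. MAPK feedback genes rose in 7 and fell in 8 of 18 cases (7 and 8 adjusted over the list alone), with the phosphatase DUSP4 at -0.88. DNA replication genes (4 higher, 10 lower of 27), unfolded protein and amino acid stress genes (5 and 10 of 22), cholesterol synthesis genes (3 and 2 of 15), heat shock genes (3 and 3 of 12) and reference genes (0 and 4 of 10) did not pass either. Adjusted over the list alone these counts were 4 and 13, 5 and 13, 5 and 3, 3 and 3, and 0 and 4. Markers of other cell types changed singly: ITGAM, a leukocyte integrin, rose by 0.78 from a mean of 4.68, and the endothelial ROBO4 by 0.98 from 6.84. Of 13 leukocyte markers 1 rose and 1 fell (1 and 0 adjusted over the list alone), and of 10 endothelial markers 3 rose and 1 fell (3 and 1). Of 14 luminal markers 3 rose and 4 fell (3 and 5 adjusted over the list alone), ELF3 at 2.49 and GATA3, a luminal transcription factor, at -1.33. Of 7 basal markers 1 rose and 3 fell (1 and 3), with the receptor EGFR at 0.71. Median and mean differed in sign for the epithelial, extracellular matrix, MAPK feedback, luminal and basal lists, none of which passed the test. On moderated statistics the epithelial list passed with the dimmest 50% of genes left out (median 0.099) and with only the 2 groups compared (-0.095), over a range of adjusted p from 0.00951 to 0.365 in 28 alternatives.

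Position codes in the array names place 2 arrays of each of these groups in column 7. Within it 5488 genes changed with TNFα. The within-column medians were 2.16 for NF-kB genes and 2.58 for interferon-stimulated genes.

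The c-Jun siRNA effect with vehicle shows which genes change with the knockdown without added TNFα. Beside the fall of JUN (-0.52 ± 0.032), RGS5, a regulator of G-protein signalling, rose by 3.85 ± 0.062 (SE, n = 3 per group), and the chemokines CCL5 and CXCL8 rose by 3.07 ± 0.041 and 2.47 ± 0.061 with no TNFα given. The adhesion receptor ADGRG6 rose by 3.06, the vitamin D receptor VDR by 2.61, the retinal reductase DHRS3 by 2.34, the transglutaminase TGM2 by 2.23, and PADI2, GFRA1 and PLEKHA6 by 2.18, 2.16 and 2.15. Lower were PDGFRL (-1.85 ± 0.061) and the desmosomal protein gene DSP (-1.72 ± 0.047). ADAMTS14, SLITRK2, PDE3A, the metallothionein MT1F, the amino acid transporter SLC7A2, BMP6 and the clock gene NPAS2 fell too, from -1.85 to -1.66. The standard errors of the 126 genes named by the rule ran from 0.028 to 0.13. In all 5183 genes changed, 2583 higher and 2600 lower, and 112 rose and 48 fell at least 2-fold. With each array centred on its median, 38.8% of the changed genes were lower, against 50.2% as deposited.

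Several inflammatory lists were higher with c-Jun siRNA and vehicle. Of 22 NF-kB early response genes 16 rose and 1 fell (16 and 2 adjusted over the list alone; median 0.43, adjusted p = 2.4e-09), with NFKBIA at 1.27, NFKB2 at 1.18, REL at 1.08 and IER3 at 0.96. Of 28 cytokines and chemokines 12 rose and none fell (14 adjusted over the list alone; adjusted p = 4.34e-06), with the monocyte chemokine CCL2 at 1.84 and the growth factor CSF1 at 0.90. MHC class I presentation rose in 11 of 13 genes (12 adjusted over the list alone; median 0.81, adjusted p = 3.44e-15), with PSMB9 at 1.84, TAP1 at 1.59, ERAP1 at 1.13 and HLA-B at 0.92. Of 28 interferon-stimulated genes 13 rose and 1 fell (14 and 1 adjusted over the list alone), with XAF1 at 1.12, IFIT1 at 0.83 and USP18 at 0.75. That call was not kept, with adjusted p = 0.000197 against adjusted p = 0.209 with an estimated correlation.

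YAP/TEAD target genes and stress genes rose too with the knockdown and vehicle. Of 21 YAP/TEAD target genes 12 rose and none fell (13 adjusted over the list alone; median 0.25, adjusted p = 8.76e-09), with CCN1 at 1.99, AJUBA at 1.45, CRIM1 at 1.42 and AMOTL2 at 1.31. In the unfolded protein and amino acid stress list 15 of 22 rose and 2 fell (17 and 2 adjusted over the list alone; adjusted p = 7.26e-08), with the glutathione-degrading CHAC1 at 0.95, the cystine transporter SLC7A11 at 0.66 and the serine synthesis enzyme PSAT1 at 0.61. Of 18 mesenchymal genes 10 fell and 3 rose (12 and 3 adjusted over the list alone), with the transcription factors SNAI2 at -1.44 and PRRX1 at -0.50 and fibronectin FN1 at -0.45. Its adjusted p = 0.000594 became adjusted p = 0.151 with an estimated correlation. DNA replication genes rose in 13 and fell in 2 of 27 cases (13 and 2 adjusted over the list alone), with CDC6 at 0.44 and TYMS at 0.43, at adjusted p = 0.0055 and adjusted p = 0.192 with an estimated correlation. A test of these genes on moderated statistics alone did not pass without c-Jun siRNA vehicle replicate 3 (adjusted p = 0.0648, median 0.084 against 0.090), without the mean-variance trend (0.0731) or with the dimmest 30% or 50% of genes left out (0.0946 and 0.174), over a range of 0.0218 to 0.174 in 28 alternatives. Mitosis genes fell in 9 and rose in 1 of 27 cases (10 and 1 adjusted over the list alone), with UBE2C at -0.29, at adjusted p = 0.0205 and adjusted p = 0.509 with an estimated correlation. Cholesterol synthesis genes fell in 8 and rose in 2 of 15 cases (9 and 2 adjusted over the list alone), with MVD at -0.35 and LSS at -0.30, at adjusted p = 0.00612 and adjusted p = 0.0556 with an estimated correlation. On moderated statistics this call ended without the mean-variance trend (adjusted p = 0.0525) and with the dimmest 30% or 50% of genes left out (0.0597 and 0.0833), over a range of 0.0127 to 0.0833 in 28 alternatives. Hypoxia and glycolysis genes rose in 9 and fell in 3 of 20 cases (9 and 3 adjusted over the list alone), with ADM at 0.88 and EGLN3 at 0.89 against CA12 at -1.12, at adjusted p = 0.0105 and adjusted p = 0.151 with an estimated correlation.

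Within the AP-1 family the knockdown with vehicle left 5 of 16 genes higher and 6 lower (the same counts adjusted over the list alone), and the list did not pass. The repressor JDP2 rose by 0.74, JUNB by 0.44, MAFF by 0.45 and FOSL1 by 0.28, while BATF3 (-0.32) and ATF2 (-0.29) fell. AP-1 target genes were split, 8 higher and 5 lower of 25 (8 and 5 adjusted over the list alone; adjusted p = 0.0588), with THBS1 at 0.93, PLAU at 0.91 and cyclin CCND1 at 0.86. A second, dimmer CCND1 probe set gave -0.017 and did not pass. Among MAPK feedback genes 5 rose and 4 fell of 18 (6 and 4 adjusted over the list alone), with the immediate early gene EGR1 at -1.21. Epithelial genes rose in 3 and fell in 1 of 18 cases (3 and 1), CLDN1 at 1.24 and the keratin KRT18 at 0.77 against DSP. Extracellular matrix genes (12 higher, 9 lower of 28; 13 and 10 adjusted over the list alone) included TNC at -0.99. TNF receptor components (6 and 3 of 17), p53 targets (6 and 2 of 15, with CDKN1A at -0.84) and apoptosis regulators (8 and 1 of 21, with PMAIP1 at 1.51) did not pass as lists. Adjusted over the list alone they counted 6 and 4, 6 and 2, and 8 and 2. In the test on moderated statistics apoptosis regulators passed (adjusted p = 0.021, over a range of 0.00692 to 0.0512 in 28 alternatives), and so did AP-1 target genes (0.00563, over a range of 0.00326 to 0.0289). The heat shock (1 and 3 of 12), reference (3 and 2 of 10), leukocyte (1 and 0 of 13), endothelial (3 and 1 of 10), luminal (3 and 1 of 14) and basal (2 and 2 of 7) lists did not pass either. Adjusted over the list alone, heat shock genes counted 2 and 3 and leukocyte markers 0 and 0, and the others the same as over all genes. Among endothelial markers ROBO4 rose by 1.05 from 6.84 and TEK by 0.93 from 5.78. With the dimmest 30% of genes left out that list passed on moderated statistics (median 0.93 against 0.0058, over a range of adjusted p from 0.0238 to 0.456 in 27 alternatives). Median and mean differed in sign for the AP-1 family, MAPK feedback, epithelial, extracellular matrix and basal lists.

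The 3 arrays of this c-Jun siRNA group share position column 5 with 1 control array. Within that column 3493 genes changed, JUN by -0.53, with the lone control array assumed to vary like the other groups. The column as a fixed block left 3448 genes.

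The c-Jun siRNA effect with TNFα shows which genes change with the knockdown while the cytokine acts. JUN (-0.71 ± 0.032), the transcription factor gene SNAI2 (-2.01 ± 0.051, SE, n = 3 per group) and the Notch ligand gene JAG1 (-1.61 ± 0.036) were lower. SEMA6A, a guidance cue (-2.02 ± 0.11), the plasminogen activator PLAT (-1.89 ± 0.097), the chromatin organiser SATB1 (-1.85) and the pentraxin PTX3 (-1.75) were lower as well. So were RTL9 (-1.73), ADRA1D (-1.61), DSP (-1.61) and the T-box factor EOMES (-1.58). The acute-phase protein gene SAA2 rose by 3.67 ± 0.13, and its second probe set, with a mean of 3.88, by 0.54. RGS5 rose by 3.55 ± 0.062, ADGRG6 by 2.93, DHRS3 by 2.90, VDR by 2.56 and the vasoconstrictor EDN1 by 2.47 ± 0.074. ITM2A, the tryptophan dioxygenase TDO2 and the decoy receptor IL22RA2 rose by between 1.97 and 2.14. In all 5116 genes changed, 2534 higher and 2582 lower, with 74 at least 2-fold higher and 74 at least 2-fold lower. The standard errors of the 122 genes named by the rule ran from 0.029 to 0.13.

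Under TNFα the interferon-stimulated genes were lower with c-Jun siRNA, 18 of 28 with none higher (20 lower and 1 higher adjusted over the list alone; median -0.37). GBP2 was at -0.85, and IFIT1, IFIT5 and IFIH1, which act against viral RNA, at -0.79, -0.79 and -0.78. The list gave adjusted p = 1.02e-08, and adjusted p = 0.0621 with an estimated correlation. NF-kB early response genes went both ways, 4 higher and 10 lower of 22 (5 and 10 adjusted over the list alone), with TNIP3 at -1.13, TNFAIP8 at -0.69 and TNIP1 at 0.50. So did cytokines and chemokines, 9 higher and 6 lower of 28 (11 and 6 adjusted over the list alone), with CXCL5 at 1.01 and CCL5 at 0.64. Neither list passed. MHC class I presentation genes were higher in 7 and lower in 1 of 13 cases (7 and 1 adjusted over the list alone), with PSMB9 at 0.81 and ERAP1 at 0.38, at adjusted p = 0.0067 and adjusted p = 0.0892 with an estimated correlation. The unfolded protein and amino acid stress list rose in 18 of 22 genes and fell in 1 (19 and 1 adjusted over the list alone; median 0.26, adjusted p = 3.49e-10), with CHAC1 at 1.11 and PSAT1 at 0.59. YAP/TEAD target genes rose in 11 and fell in 3 of 21 cases (the same counts adjusted over the list alone; adjusted p = 3.28e-05), with AJUBA at 1.45, CCN2 at 1.17 and CCN1 at 1.02.

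Mesenchymal genes were lower in 8 and higher in 3 of 18 cases with c-Jun siRNA under TNFα (8 and 3 adjusted over the list alone), SNAI2 and ZEB2 beside FN1 at -0.60 and CDH11 at -0.54. The list gave adjusted p = 0.0024, and adjusted p = 0.187 with an estimated correlation. DNA replication genes rose in 12 and fell in 2 of 27 cases (13 and 3 adjusted over the list alone), with CDC6 at 0.55 and TYMS at 0.47, at adjusted p = 0.00249 and adjusted p = 0.161 with an estimated correlation. AP-1 target genes were higher in 6 and lower in 11 of 25 cases (6 and 11 adjusted over the list alone), with MMP9 at -1.11 and PLAU at 0.70. In the AP-1 family 1 gene rose and 5 fell of 16 (3 and 5 adjusted over the list alone), with FOSL2 at 0.23 and MAFF at -0.32, and JUNB (0.12) and FOSL1 (0.035) did not pass. Epithelial genes rose in 3 and fell in 1 of 18 cases (3 and 1), with the cadherin CDH1 at 0.95 from a low mean of 4.54 and KRT18 at 0.72. Extracellular matrix genes (9 and 10 of 28; 10 and 10 adjusted over the list alone) included TNC at -1.06, TIMP3 at -0.88 and COL3A1 at -0.71. Hypoxia genes (9 and 4 of 20; 11 and 4 adjusted over the list alone) included the vasodilator peptide gene ADM at 1.62. None of the other lists passed: MAPK feedback (4 and 7 of 18, SPRY2 at 0.63), TNF receptor components (2 and 4 of 17), mitosis (4 and 5 of 27), p53 targets (5 and 3 of 15, CDKN1A at -0.93), apoptosis (8 and 5 of 21), cholesterol (3 and 4 of 15), heat shock (3 and 0 of 12), reference (4 and 1 of 10), leukocyte (0 and 0 of 13), endothelial (2 and 0 of 10), luminal (3 and 2 of 14) and basal markers (2 and 2 of 7). Adjusted over the list alone their counts were the same, and 1 leukocyte marker had an unadjusted limma p under 0.05. In the test on moderated statistics 3 more lists passed: hypoxia (adjusted p = 0.00713, over a range of 0.00127 to 0.0376 in 28 alternatives), extracellular matrix (0.0431, over 0.0225 to 0.234) and apoptosis genes (0.0475, over 0.0212 to 0.139). The matrix and apoptosis calls ended in many alternatives, most of them with single arrays left out. Among the others were the mean of a gene's probe sets (0.234) for the matrix list. For the apoptosis list they included the replicate block (0.0706) and the position column as a fixed block (0.0739). The median and mean of the p53 list differed in sign.

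Within position column 9 (2 c-Jun siRNA arrays against 1 control) 3182 genes changed under TNFα, and within column 7 (1 against 2) 3449 changed. The lone arrays were assumed to vary like the other groups. JUN changed by -0.74 and -0.72 in these columns, and the interferon-stimulated median was -0.32 and -0.49.

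**Figure D2:**
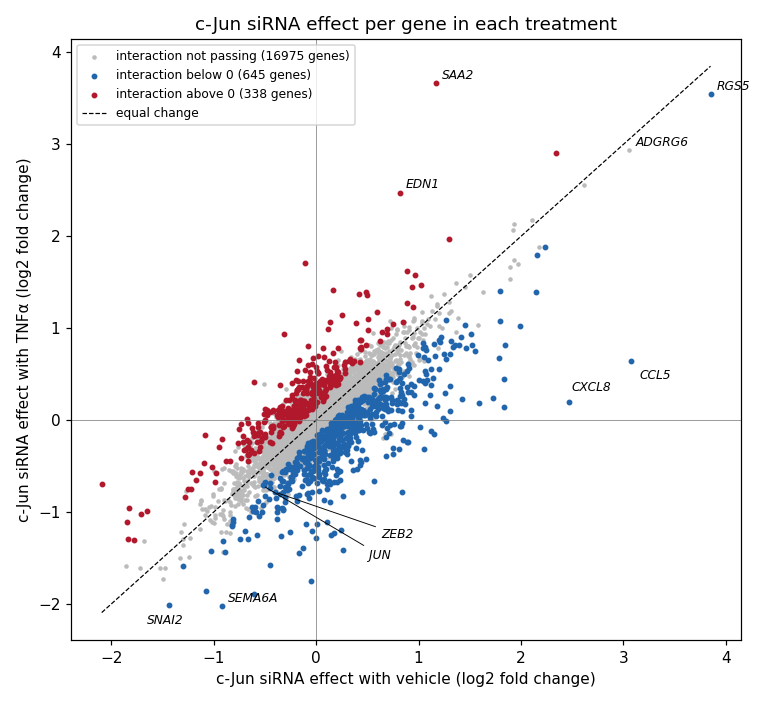
Log2 fold change by c-Jun siRNA with vehicle (x axis) and with TNFα (y axis) for 17958 genes, coloured by the test of the difference between the effects, with a dashed line of equal change. CCL5 lies far below the line (3.07 against 0.64), SAA2 far above it (1.17 against 3.67), and RGS5 near it (3.85 against 3.55).

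The knockdown changed many of the same genes in both treatments. Of the 5183 and 5116 genes, 3369 changed in both in the same direction: 1747 higher, against 364.5 for independent calls, and 1622 lower, against 373.8. Another 104 changed in opposite directions, against 738.3. These comparisons share no array, but both use the same variance estimate per gene. Calls also gather in brighter genes: 4238 of the 5183 with vehicle were called again with the dimmest 50% of genes left out. The numbers for independent calls may therefore be too low. Across genes, which are not independent replicates, the log2 fold changes of the knockdown in both treatments had a Pearson r of 0.749. ADGRG6, VDR, DSP and AJUBA were examples with nearly equal values in both.

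TNFα with c-Jun siRNA shows the response that remains with less JUN. CXCL10 rose by 7.49 ± 0.10 (SE, n = 3 per group), VCAM1 by 6.28 ± 0.057, TNFAIP2 by 6.25 ± 0.067, TNFAIP6 by 6.24 ± 0.078 and the complement gene C3 by 4.32 ± 0.083. MX1, XAF1, OAS2, GBP4 and SAMD9L rose by 4.64, 4.30, 4.27, 4.15 and 3.95. Falls were deepest in PPDPFL (-2.80 ± 0.11), the angiogenic factor PGF (-2.71 ± 0.071), PCDH18 (-2.39), BRINP1 (-2.32) and SLITRK6 (-2.30). TMEM37, BOC, PPP1R3C, the lipoprotein lipase inhibitor ANGPTL4 and PDE8B followed, from -2.08 to -1.98. The standard errors of the 114 genes named by the rule ran from 0.028 to 0.17. In all 5320 genes changed, 2036 higher and 3284 lower, with 250 at least 2-fold higher and 86 at least 2-fold lower. With each array centred on its median 1667 were higher and 3904 lower. With control and c-Jun siRNA TNFα changed 4225 genes in the same direction, 1607 higher (281.9 for independent calls) and 2618 lower (718.7), and 39 in opposite directions (900.2). Across genes the Pearson r was 0.901, with no shared array. As for the knockdown, the same variance estimate per gene served both comparisons, so the numbers for independent calls may be too low.

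The NF-kB, interferon-stimulated and MHC class I lists rose at smaller medians than with control siRNA. The cytokine list did not, but its order depends on the processing. Over 28 alternatives its median ran from 1.30 to 3.63 with control siRNA and from 1.44 to 3.02 with c-Jun siRNA. All 22 NF-kB early response genes rose (22 adjusted over the list alone; median 1.54, adjusted p = 3.83e-38), with TNFAIP3 at 3.24 and the adhesion molecule ICAM1 at 2.53. Of 28 cytokines and chemokines 23 rose (23 adjusted over the list alone; median 1.58, adjusted p = 1.82e-27), with CCL20 at 3.32 and CXCL8 at 3.32, and of 28 interferon-stimulated genes 27 rose (27 higher and 1 lower adjusted over the list alone; median 1.76, adjusted p = 5.1e-37). All 13 MHC class I genes rose (13 adjusted over the list alone; median 0.98, adjusted p = 1.02e-20), with TAP1 at 1.76. Hypoxia and glycolysis genes fell in 17 and rose in 1 of 20 cases (17 and 1 adjusted over the list alone; median -0.38, adjusted p = 6.1e-11), with PFKFB4 at -1.84 and VEGFA at -0.73. Cholesterol synthesis genes rose in 9 of 15 cases and none fell (10 adjusted over the list alone; adjusted p = 9.04e-05), with HMGCS1 at 0.61 and STARD4 at 0.65. AP-1 target genes rose in 13 and fell in 1 of 25 cases (14 and 1 adjusted over the list alone; adjusted p = 5.83e-05), with MMP1 at 1.96. TNF receptor components rose in 8 and fell in 1 of 17 cases (8 and 1; adjusted p = 0.000739), with CYLD at 1.62, and apoptosis regulators rose in 11 and fell in 4 of 21 cases (11 and 4; adjusted p = 4.15e-05), with the death receptor FAS at 1.09. The AP-1 family rose in 7 and fell in 2 of 16 cases (8 and 2 adjusted over the list alone), with JUNB at 0.98, MAFF at 0.86 and JDP2 at -0.51, at adjusted p = 0.00897 and adjusted p = 0.253 with an estimated correlation. Of the 15 other lists none passed, with SNAI2 at -0.90, CDH11 at -1.01, DUSP4 at -1.03, TIMP3 at -1.58 and ELF3 at 2.00 among their members. Higher and lower genes in them numbered 7 and 6 for MAPK feedback, 5 and 9 for mesenchymal, 4 and 1 for epithelial, 6 and 12 for matrix, 8 and 4 for YAP/TEAD, 3 and 5 for mitosis, 2 and 10 for DNA replication and 6 and 3 for p53 genes. They were 4 and 10 for the stress list, 3 and 2 for heat shock, 1 and 4 for reference, 1 and 0 for leukocyte, 1 and 0 for endothelial, 3 and 3 for luminal and 2 and 3 for basal genes. Adjusted over the list alone they were the same, except for MAPK feedback 7 and 7, mesenchymal 6 and 10, matrix 7 and 12, YAP/TEAD 8 and 5, and heat shock 5 and 2. In the p53 list, with CDKN1A at 1.15, the median (-0.010) and the mean (0.22) differed in sign, as they did in the extracellular matrix, luminal and basal lists. On moderated statistics the p53 list passed (adjusted p = 0.0029, over a range of 0.00193 to 0.0209 in 28 alternatives). No position column holds arrays of both these groups, and with the column as a fixed block 2376 genes changed, and the same-direction overlap of the TNFα effects was 2194.

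**Figure D3:**
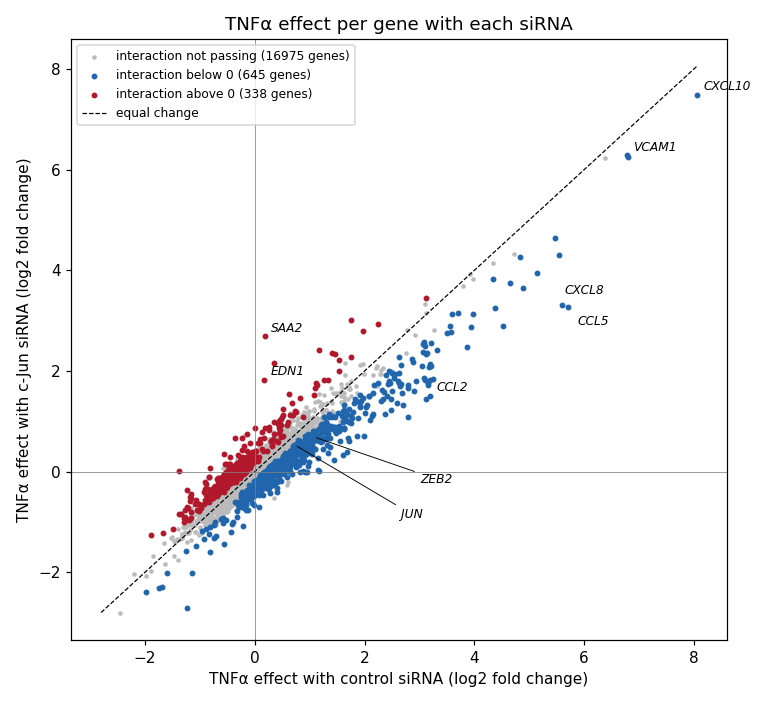
Log2 fold change by TNFα with control siRNA (x axis) and with c-Jun siRNA (y axis) for 17958 genes, coloured by the test of the difference, with a dashed line of equal change. CCL5 rose by 5.71 and 3.28 and CXCL10 by 8.06 and 7.49, while SAA2 (0.19 and 2.69) and EDN1 (0.17 and 1.83) lie above the line.

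The interaction asks whether the TNFα response itself differs with c-Jun siRNA. The TNFα response of CCL5 differed by -2.43 ± 0.058 log2 units (SE, n = 3 per group), that of CXCL8 by -2.27 ± 0.086, that of CCL2 by -1.69 ± 0.055 and that of TAP1 by -1.40 ± 0.047. The kinase gene NUAK2 (-1.38), PARP14 (-1.37), NFKBIA (-1.28), CSF1 (-1.13), CLDN1 (-1.22) and CCN1 (-0.97) complete the 10 genes with the smallest p. The standard errors of the 78 genes named by the rule ran from 0.043 to 0.15. In CCL5 the start level rose from 5.90 to 8.97 with c-Jun siRNA, and the level with TNFα from 11.60 to 12.25. For IFIT1 (-1.62), the start level rose from 5.16 to 5.99 and the level with TNFα fell from 9.68 to 8.89. In all 983 genes passed, 645 with a lower and 338 with a higher response with c-Jun siRNA, and 44 and 7 of these differed at least 2-fold. With the position column as a fixed block 531 genes passed. With each array centred on its median, 688 genes had a lower and 227 a higher response.

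Several lists raised by TNFα had a smaller response with c-Jun siRNA, while the apoptosis (median 0.033, adjusted p = 0.847), p53 (-0.072, 0.0592) and AP-1 family (-0.035, 0.222) lists did not pass. Of 22 NF-kB early response genes 15 had a lower response and none a higher (18 adjusted over the list alone; median -0.54, adjusted p = 6.14e-29), with TNFAIP3 at -1.13, NFKB2 at -1.02 and TNIP3 at -1.03. Of 28 interferon-stimulated genes 22 were lower (23 adjusted over the list alone; median -0.69, adjusted p = 8.01e-31), with XAF1 and IFIH1 both at -1.23. MHC class I presentation was lower in 11 of 13 genes (12 adjusted over the list alone; median -0.53, adjusted p = 3.01e-27), with PSMB9 at -1.03 and HLA-B at -0.82, and cytokines and chemokines in 10 of 28 (11 adjusted over the list alone; adjusted p = 2.27e-09). The median of the cytokine list was -0.089, from -0.680 to 0 over 28 alternatives and -0.178 with the position column as a fixed block. Its TNFα medians were 1.52 with control and 1.58 with c-Jun siRNA. Over the alternatives they ran from 1.30 to 3.63 and from 1.44 to 3.02, in the reverse order where the control median was highest. AP-1 target genes were lower in 9 of 25 cases (11 lower and 1 higher adjusted over the list alone; adjusted p = 1.02e-07), with MMP9 at -1.21 and MMP1 at -0.67. YAP/TEAD target genes were lower in 4 of 21 (5 adjusted over the list alone; adjusted p = 4.21e-05), with AMOTL2 at -0.59. Cholesterol synthesis responded more, with 3 genes higher and 1 lower of 15 (6 and 1 adjusted over the list alone; adjusted p = 0.000256), HMGCS1 at 0.31 and IDI1 at 0.30. Of 27 mitosis genes 2 were higher (4 adjusted over the list alone) at adjusted p = 0.00076, and adjusted p = 0.296 with an estimated correlation. TNF receptor components were lower in 3 of 17 cases (3 adjusted over the list alone), with CYLD at -0.69, at adjusted p = 0.0285 and adjusted p = 0.151 with an estimated correlation. Extracellular matrix genes were lower in 6 and higher in 1 of 28 (8 and 3 adjusted over the list alone), with COL3A1 at -0.57, at adjusted p = 0.0475 and adjusted p = 0.387 with an estimated correlation. In the test on moderated statistics the receptor call ended without c-Jun siRNA TNFα replicate 2 (adjusted p = 0.0822), control siRNA TNFα replicate 1 (0.0532) or control siRNA vehicle replicate 1 (0.0756). The matrix call ended without c-Jun siRNA TNFα replicate 2 (adjusted p = 0.0556), c-Jun siRNA vehicle replicate 1 (0.0709), control siRNA TNFα replicate 1 (0.14) or control siRNA vehicle replicate 2 (0.0643). With the dimmest 30% or 50% of genes left out both calls ended, the receptor call at 0.0814 and 0.127 and the matrix call at 0.0672 and 0.139. The matrix call also ended with the mean of a gene's probe sets (0.0708). Over 28 alternatives these ran from 0.0155 to 0.127 and from 0.0122 to 0.14.

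Other lists showed no joint difference of response, and single genes differed within them. In the AP-1 family 4 of 16 genes had a lower response (5 lower and 1 higher adjusted over the list alone), with MAFF at -0.77 and JUNB at -0.32. SNAI2 fell further with TNFα when c-Jun was knocked down (-0.57), as did CDH11 (-0.27), while EGR1 differed by 0.65, ADM by 0.73, DDIT4 by 0.52 and the glucose transporter SLC2A1 by -0.64. PMAIP1 differed by -0.58 and the death receptor TNFRSF10B by -0.31. Higher and lower responses numbered 1 and 4 of 18 for mesenchymal, 0 and 1 of 18 for epithelial, 2 and 3 of 18 for MAPK feedback, 1 and 3 of 15 for p53 and 2 and 2 of 21 for apoptosis genes. They were 1 and 1 of 22 for the stress list, 4 and 3 of 20 for hypoxia, 1 and 0 of 12 for heat shock and 1 and 0 of 7 for basal genes. The DNA replication, reference, leukocyte, endothelial and luminal lists held 0 genes that passed in limma over all genes, and 1, 2, 0, 4 and 3 at an unadjusted p under 0.05. Adjusted over the list alone the counts were the same, except for mesenchymal (3 and 5), MAPK feedback (5 and 5), apoptosis (2 and 3), hypoxia (6 and 3) and endothelial genes (1 and 3). Median and mean differed in sign for the mesenchymal, MAPK feedback, apoptosis, endothelial, luminal and basal lists, none of which passed. On moderated statistics some of these lists passed under an alternative: epithelial with the dimmest 50% of genes left out (median -0.052), p53 with floored values (-0.072) and AP-1 family without c-Jun siRNA vehicle replicate 3 (-0.064). Over 28 alternatives their adjusted p-values ran from 0.00432 to 0.896, from 0.0427 to 0.21 and from 0.0404 to 0.386.

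**Figure D4:**
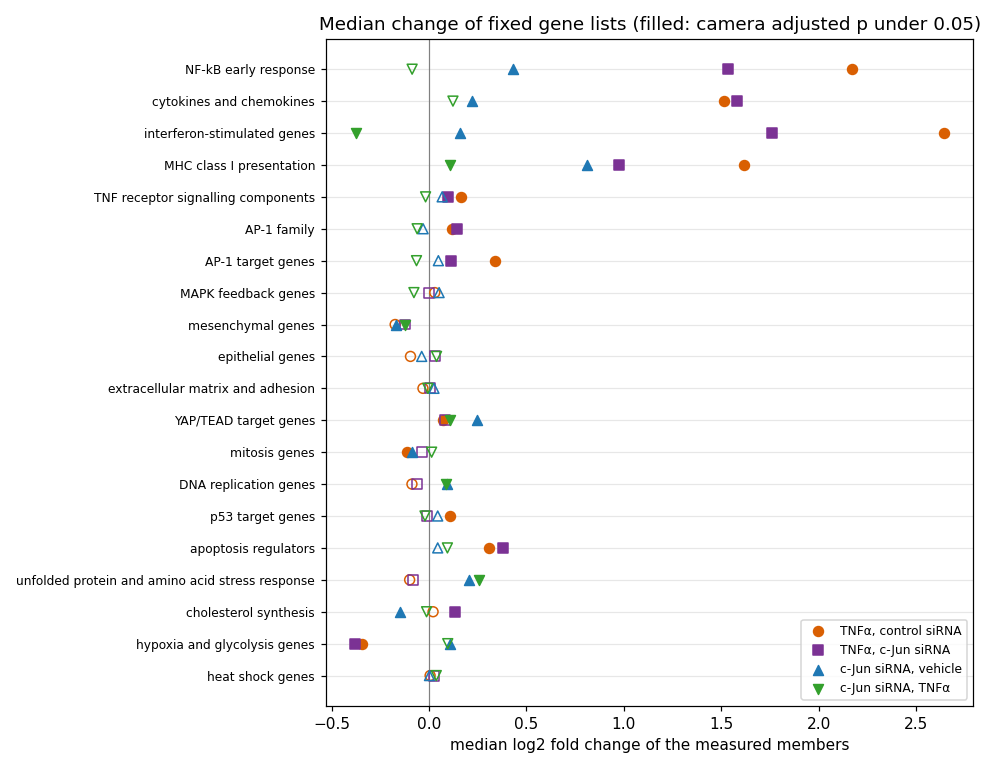
Median log2 fold change of the measured members (x axis) of 20 fixed gene lists (y axis) in the 4 pairwise comparisons, filled where the camera adjusted p was under 0.05. The NF-kB list lies at 2.17 for TNFα with control siRNA and 1.54 with c-Jun siRNA, and the interferon-stimulated list at 0.16 and -0.37 for the c-Jun siRNA effect with vehicle and with TNFα.

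Genes raised by TNFα were followed through the knockdown. Of the 2486 raised genes, 831 were lower with c-Jun siRNA under TNFα and 563 were higher, against 357.4 and 350.8 for independent calls. With vehicle 906 of them were higher and 396 lower with c-Jun siRNA, against 357.6 and 359.9. Each of these pairs of comparisons shares its control arrays, so part of any excess may come from them. In 20 simulations without a knockdown effect at most 1 gene fell into each of the 4 sets, but these call almost no knockdown genes and give no expected number. In 20 further simulations, chosen after seeing the data, the called effects were kept, those of c-Jun siRNA were shuffled among genes of like expression, and the control arrays stayed shared. They gave 414 to 470 raised genes lower and 384 to 474 higher under TNFα, and 432 to 499 higher and 400 to 448 lower with vehicle. These simulations called fewer genes than the data, so their ranges are somewhat low. For TNFα they called 5990 to 6092 (6416 in the data). For c-Jun siRNA they called 4672 to 4772 with TNFα (5116) and 4727 to 4850 with vehicle (5183). The response itself was smaller in 532 of the 2486 raised genes, among them CCL5, TNFAIP3, IFIT1 and TAP1, and larger in 52, against 89.3 and 46.8 for independent calls. Of the 3930 lowered genes, 242 had a higher and 49 a lower interaction, against 74 and 141.2. These comparisons share the control siRNA arrays. In 20 simulations like the last, with the called interactions shuffled too, the sets held 102 to 138, 38 to 66, 67 to 104 and 143 to 187 genes. They too called fewer interaction genes, 833 to 897 against 983 in the data. Of the 322 genes raised at least 2-fold, the response with c-Jun siRNA was a median 0.753 of that with control siRNA (quartiles 0.609 and 0.916), and of the 101 lowered at least 2-fold it was 0.851. Both sets were chosen by the control siRNA response, which by itself can pull such ratios below 1. No set chosen by the c-Jun siRNA response was tried.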

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

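The tests of carried-over TNFα, of an antiviral response, of the higher level without TNFα, of the genes near a ceiling, of a repeated array and of the position column, and the splits on values without the siRNA and TNFα effects were chosen only after the result was seen. The TNFα response differed between the siRNAs by a test of the difference in 983 genes. The 10 genes with the smallest p were CCL5 (-2.43), CCL2 (-1.69), TAP1 (-1.40), CXCL8 (-2.27), CLDN1 (-1.22), CCN1 (-0.97), NUAK2 (-1.38), CSF1 (-1.13), PARP14 (-1.37) and NFKBIA (-1.28), each with a smaller log2 response under c-Jun siRNA. Of 100 splits drawn from the 200 ways to place the siRNA labels within each treatment, 3 gave as many genes, the real one included, the highest other 6633 and the next 1006. The split with 6633 genes, several times the real count, swaps the siRNA labels in one treatment, so it adds the siRNA effects of both, which is a structure of the samples. Splits that mix the siRNAs put their effect into the residual, so the other drawn splits, with a median of 0 genes by limma and 463 at an unadjusted p under 0.05, do not measure chance. On values without the additive siRNA and TNFα effects, 1 of the same 100 splits, the real one, gave as many genes. The highest other gave 2. At an unadjusted p under 0.05 the real split gave 2956 genes there, the highest other 1954 and the median of the others 767. Taking out the siRNA effect empties the split that swaps the labels. The difference of response stays in these values, and splits that mix the siRNAs put it into the residual. These splits therefore do not measure chance either, and do not exclude it.

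For the pairwise comparisons, 10 splits of 6 arrays are too few for a share under 0.05. The real splits gave 6416 genes for TNFα with control siRNA, 5183 for c-Jun siRNA with vehicle, 5116 for c-Jun siRNA with TNFα, 5320 for TNFα with c-Jun siRNA, and 831 TNFα-raised genes lower with c-Jun siRNA. In each, 1 split reached the real value and the highest other gave 0 by limma, and at most 629, 901, 766 and 931 genes at an unadjusted p under 0.05 in the 4 pairwise comparisons.

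Signal also appeared in probe sets left out of the comparisons. Of 2055 probe sets with several gene symbols, 431 changed with TNFα and control siRNA, 380 with c-Jun siRNA and vehicle and 299 with c-Jun siRNA and TNFα. Of 12061 probe sets with no gene symbol, 685, 656 and 493 changed in the same comparisons.

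Inflammatory genes were higher with c-Jun siRNA and no TNFα. The position column of the arrays is argued against as the whole cause. With it as a fixed block the genes called fell from 5183 to 3448. The NF-kB list, fixed beforehand, kept a median of 0.391 against 0.430 (adjusted p = 1.84e-13 on moderated statistics, over a range of 3.29e-17 to 4.12e-10 in 28 alternatives), and the MHC class I list one of 0.789 against 0.808. These blocked values rest on the 1 control array in column 5, and a part played by the column stays open. TNFα that reached the c-Jun siRNA vehicle samples may contribute: of the 50 genes most raised by TNFα, 35 were higher, 14 did not pass and 1 was lower, with changes from -0.92 to 3.07, and neither reading is excluded. An antiviral response to the siRNA also stays open, with 46.4% of the interferon-stimulated list called higher against 72.7% of the NF-kB list. An effect of less c-Jun on these genes is the biological explanation the design names, and it was not separated from these. Nor was it separated from other effects of the siRNA pool, since no other c-Jun siRNA was used.

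The TNFα response of raised genes was smaller with c-Jun siRNA. A signal ceiling was looked for above log2 12, where 3.20% (17) of the 532 genes lay with TNFα and control siRNA. The median level of the 532 in that group was 9.37, and the highest value of any probe set was 13.97. No calibration set the level of 12. TAP1 (11.51 with control and 11.70 with c-Jun siRNA) and CXCL8 (11.41 and 11.61) lay just below it. A ceiling cannot make a level lower, so it is argued against for the 264 of the 532 called lower with c-Jun siRNA under TNFα. Of the 18 genes above log2 12 with TNFα under either siRNA, 6 were called lower and 7 higher with c-Jun siRNA under TNFα. For the genes not called lower a ceiling stays open. The 18 include CLDN1 (12.96 with control and 12.98 with c-Jun siRNA), CCL2 (12.66 and 12.80), NFKBIA (12.60 and 12.59), CSF1 (12.38 and 12.14) and CCL5 (11.60 and 12.25). One scaling of every TNFα effect is argued against as the whole cause: after scaling by the median ratio of 0.753, 41.6% (134) of the 322 genes raised at least 2-fold still differed, 67 above and 67 below. Less TNFα acting need not scale every gene alike, so this test cannot decide on it, and it stays open. Of the 532, 63.9% (340) were called higher with vehicle, while 191 were lower with TNFα and not called higher without it. The 532 were chosen by a difference that equals the c-Jun siRNA effect with TNFα less that with vehicle. Nearly all must therefore be higher with vehicle or lower with TNFα, and 1 was neither. These counts cannot decide whether a higher level without TNFα is a cause, which stays open. A dependence of these genes on c-Jun stays open as well.

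The name of the third array of the c-Jun siRNA TNFα group reads as a second run of replicate 1. The SD over genes of their log2 difference was 0.121, against 0.119 to 0.142 for the other 11 pairs within groups, 2 of which lay below it. A repeat run of replicate 1 therefore stays open. No biological explanation was tested for this array.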

How the results depend on the processing

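The comparisons within a position column are tests chosen only after the result was seen. A threshold of at least 1.5-fold left 1167 genes for TNFα with control siRNA, 665 for c-Jun siRNA with vehicle, 613 for c-Jun siRNA with TNFα, 914 for TNFα with c-Jun siRNA, 207 for the interaction, 92 TNFα-raised genes lower with c-Jun siRNA, and overlaps of 369 (c-Jun siRNA) and 756 (TNFα). An adjusted p under 0.01 left 553 interaction genes. Both thresholds are stricter by construction. The position column as a fixed block gave 3448 genes for c-Jun siRNA with vehicle, 2376 for TNFα with c-Jun siRNA, 531 for the interaction and an overlap of TNFα effects of 2194. No column holds arrays of both groups of TNFα with c-Jun siRNA. With the block that effect is estimated only through the other groups, with less precision. How much of the drop this explains was not tested. An F test of the column called 0 genes in limma, and 1075 at an unadjusted p under 0.05. Array medians nevertheless followed the column: 5.623 to 5.633 in column 5, 5.639 to 5.661 in column 9 and 5.664 to 5.684 in column 7. Column 5 holds all c-Jun siRNA vehicle arrays. Its lone control array lay at 5.633, below the 5.6745 and 5.6762 of the other arrays in its group. Within column 9, with fewer arrays and its lone control array assumed to vary like the others, c-Jun siRNA with TNFα changed 3182 genes. Leaving out each array in turn gave 5759 to 6516 genes for TNFα with control siRNA, 4510 to 5282 and 4440 to 5190 for c-Jun siRNA with vehicle and with TNFα, 4661 to 5313 for TNFα with c-Jun siRNA and 774 to 1009 for the interaction. TNFα-raised genes lower with c-Jun siRNA numbered 712 to 851, and the overlaps 3048 to 3234 and 3814 to 4039. With replicate number as a block, which is not known to pair arrays, the interaction gave 937 genes. Over the other alternatives all 8 counts stayed within 1.5 times their value, the interaction between 710 without a mean-variance trend and 1136 with the dimmest 30% of genes left out. Medians near 0 of lists that camera did not call changed sign. The extracellular matrix median for c-Jun siRNA with TNFα became 0.0041 with centred arrays and ran from -0.021 to 0.0054 with single arrays left out. The epithelial medians became 0.099 for TNFα with control siRNA and -0.052 for the interaction with the dimmest 50% of genes left out, and both lists passed there (adjusted p = 0.00951 and 0.00432, over ranges of 0.00951 to 0.365 and 0.00432 to 0.896). The p53 median for TNFα with c-Jun siRNA became 0.017 with the fixed block and ran from -0.025 to 0.045 with single arrays left out. The mesenchymal list for TNFα with c-Jun siRNA passed with the mean of a gene's probe sets (-0.123, over a range of adjusted p from 0.0201 to 0.326). The cause of these was not tested. Of 519 called results of named genes 288 kept their call under every alternative run, 231 lost it under some and 0 reversed, by limma; of the 231, 70 lost it outside the stricter thresholds and single arrays left out. Of 52 list calls 51 held with the fixed block. Genes near the background are limited by signal, and the dim second probe sets of ZEB2, SAA2 and CCND1 gave smaller changes in the comparisons reported.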

Other observations

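The gene groups in the next paragraphs, and their tests, were chosen only after the result was seen. TNFα with control siRNA lowered homeobox genes of the HOXB and HOXC clusters, which set positional identity. Of 10 HOXB genes 8 fell and none rose (median -0.80, adjusted p = 1.59e-05, adjusted p = 0.0719 with an estimated correlation), with HOXB6 at -1.89, HOXB3 at -1.40 and HOXB5 at -1.38. All 7 HOXC genes fell (median -0.79, adjusted p = 1.81e-05, adjusted p = 0.0719 with an estimated correlation), with HOXC11 at -1.35 and HOXC9 at -1.09. Of 9 HOXD genes 0 passed in limma, and 0 at an unadjusted p under 0.05, but they started at 3.77 to 6.13, mostly below the array medians of 5.62 to 5.68, where a fall may not be seen. The dim HOXB1 (4.91) and HOXB9 (5.19) did not pass either. Of the HOXA cluster HOXA2 alone was measured here on its own probe set, at -0.69. With c-Jun siRNA 8 HOXB and 7 HOXC genes fell as well, and the interaction was above 0 in HOXB6 (0.63), HOXB5 (0.55) and HOXB2 (0.40). Hedgehog pathway genes fell with TNFα in 7 of 10 cases and rose in 1 (median -0.51, adjusted p = 0.0028, adjusted p = 0.0902 with an estimated correlation), with BOC at -2.20, the receptor PTCH1 at -1.51 and CDON at -1.30, against GLI3 at 0.57.

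Ribosome biogenesis genes rose with TNFα and control siRNA in 27 of 36 cases and fell in 1 (median 0.23, adjusted p = 3.8e-10, adjusted p = 0.0719 with an estimated correlation), with RRS1 at 0.99 and RRP12 at 0.68. Metallothioneins, which bind zinc and copper, rose with TNFα in 8 of 9 cases (median 0.64, adjusted p = 1.76e-06, adjusted p = 0.0902 with an estimated correlation). They fell with c-Jun siRNA and vehicle in 7 of 9 (median -0.35, adjusted p = 2.45e-05, adjusted p = 0.12 with an estimated correlation), with MT1F at -1.78 and MT1E at -1.14. Of 11 type I and III interferon genes 1 (IFNK) rose and 1 (IFNE) fell with TNFα and control siRNA, and IFNB1 did not pass (adjusted p = 0.553). All but IFNL3 had group means of 5.01 or less, IFNB1 of 3.49 to 3.57, below the array medians, so neither the size of a change nor its absence can be read from them. Responses that were larger with c-Jun siRNA include the acute-phase gene SAA2 (2.50) and the peptide hormone gene EDN1 (1.66). In 3 of the 4 groups SAA2 lay below the array medians, at 3.94 to 5.10, so the size of its difference is limited by the background. SAA1 passed too, but at group means of 3.22 to 4.36 its size cannot be read. The second, dimmer SAA2 probe set gave an interaction of 0.46 that did not pass (adjusted p = 0.251).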
